A study of Mus musculus with 6 samples.

How the data were processed

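RNA sequencing was analysed from leukemic blasts of 6 mouse libraries, 3 labelled Asxl1 WT and 3 labelled Asxl1 G643W on both alleles, all on a Cebpa-/p30 background. Per the labels' protocols, blasts were sorted by flow cytometry from the bone marrow of leukemic mice as CD45.2-positive cells with low Mac1 and Gr1 and without Ter119, B220 or CD3, and libraries were made with a TruSeq V2 kit. The labels number the libraries within each genotype but do not say which of them trace to separate primary leukemias, so the p-values measure the spread between these libraries, part of which may be technical.

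The authors deposited per-transcript tables from Salmon. Per the submitters' processing notes, Salmon 0.12.0 and bcl2fastq were used with the builds mm10 and GRCm38.p6, while the Salmon options and the transcript index are not given in the sources used here. Per the file headers, the deposited values are estimated counts of reads per transcript, which need not be whole, and TPM, which is scaled to transcript length and library total. Salmon divides reads that match several transcripts among them by a statistical model, so values of genes with a near-identical copy are estimates that single base differences can move. Whether strand was used in counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

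Each table held 136288 transcripts, of which 136176 carried an identifier of GENCODE M21 (GRCm38) and were summed over 53458 genes. The other 112 transcripts held at most 0.0365% of a library's reads and were left out of the tests. Of the matched transcripts, 99.2% had the same length as in that annotation, and coordinates are given from it, counted from 1. The estimated counts were summed per gene and rounded to whole numbers. Library totals ranged from 61167075 to 101189225 estimated reads. No pair of libraries agreed within sampling noise, so each library counted as 1 sample.

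Genes were kept with the defaults of filterByExpr (minimum count 10), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, genotype only, two-sided) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over all 20654 genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled read shares, given as mean ± SD of 3 libraries. For Asxl1 and Cebpa, TPM values were also compared with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 against 3.

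The tests, the alternatives, the named genes and 38 gene lists were fixed before the data were examined. The exact permutation test was named there for Asxl1 and Cebpa alone, and its use on the mean levels of lists was added. The lists covered chromatin complexes, hematopoietic and other cell types of marrow, cell cycle, ribosome, metabolism and stress. Each list had at least 5 measured members and was tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over the 38 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, were run beside it. A symbol carried by several gene entries was given to the entry with the most reads.

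Genes were named by rule: Asxl1 and Cebpa, up to 12 protein-coding genes per direction with the largest change among those past the threshold with at least 1 TPM in the higher group and no overlap between the groups, and the 5 lowest p-values where fewer than 5 qualified in a direction. The rule also took up to 2 called members per direction of each list, or the member with the lowest p where none passed, and the 5 genes with the lowest adjusted p. Alternatives were other scaling, other filters, length-scaled counts, the replicate number as a block, each library left out, limma on log2(TPM + 1) and log2(TPM + 0.1), DESeq2 1.42.0 and protein-coding genes alone. After the data had been seen, removal of a length and GC trend, the neutrophil list's mean as a covariate and robust fitting were added. Near-identical copies were sought with BLAST+ 2.17.0 as transcripts of another gene with at least 95% identity over at least 50% of the length. Only the transcript with the most reads of each gene was searched, on the same strand, so less similar copies would be missed.

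The procedure was tested on simulated counts for this comparison, over 20654 genes. Of 50 genes changed at each size, 6% were recovered at 2-fold, 20% at 4-fold, 30% at 8-fold and 70% at 16-fold, and 3 of 20424 unchanged genes were called. The simulated genes were drawn independently of each other, without any structure shared between libraries. The number of false calls need not hold for the real libraries, whose genes move together. The biological coefficient of variation was 52.8%, so changes of a few fold were mostly below what this design detects.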

Results

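Gene expression was measured by RNA sequencing in bone marrow blasts from mice with acute myeloid leukemia that lacked full-length Cebpa, the myeloid transcription factor C/EBPα, and carried its short p30 form. The blasts had either wild-type Asxl1 (WT, 3 libraries) or the G643W change in both Asxl1 alleles (G643W, 3 libraries). Asxl1 encodes a chromatin regulator that partners the deubiquitinase Bap1. Totals were 72664292, 69885969 and 76060388 estimated reads in WT libraries 1 to 3 and 61167075, 101189225 and 76981758 in G643W libraries 1 to 3. The comparison addresses how the Asxl1 change alters expression in Cebpa-mutant blasts.

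The altered genes were read first. Asxl1 (ENSMUSG00000042548; GRCm38 chromosome 2, 153345829 to 153404007, plus strand) was at 6.95, 3.68 and 7.15 TPM in the WT libraries and at 13.7, 20.2 and 15.5 TPM in the G643W libraries. The means were 5.93 ± 1.95 and 16.5 ± 3.36 TPM (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest this design allows). Part of the G643W level came from a transcript of 355 bases, at 4.65, 8.04 and 4.17 TPM from only 67, 175 and 67 estimated reads. The transcript with the most reads (6968 bases) had 5.31, 3.03 and 4.85 TPM in WT and 6.67, 8.97 and 9.59 TPM in G643W libraries. In the count model the log2 difference of Asxl1 was 0.95 ± 0.27 (SE, edgeR adjusted p = 0.454), which did not pass. Cebpa (ENSMUSG00000034957; chromosome 7, 35119293 to 35121928, plus strand) had 44.7, 64.5 and 26.9 TPM in WT and 59.0, 5.93 and 11.5 TPM in G643W libraries. The groups overlapped, with a log2 difference of -1.16 ± 0.81 (SE, edgeR adjusted p = 0.607). With 1 library left out the Cebpa difference ranged from -2.57 to -0.71. Gene totals do not show the DNA change itself, so they do not check the genotype labels.

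Few genes changed past the threshold, and those that did changed by a large factor. Of 20654 genes tested, 11 rose and 14 fell in G643W blasts, with a smallest absolute log2 fold change of 2.57 (edgeR, adjusted p under 0.05). Protein-coding genes made up 13 of the 25, of which 1 rose and 12 fell, and 10 were pseudogenes, of which 9 rose. Traip, a ubiquitin ligase of the DNA replication stress response (chromosome 9, 107950136 to 107972270), rose from 22.98 ± 6.59 to 2663 ± 528 CPM (log2 fold change 6.86 ± 0.42, edgeR adjusted p = 0.0064). Eno1b, an intronless enolase gene (chromosome 18, 48045335 to 48048412), fell from 357 ± 97.6 to 0.81 ± 0.43 CPM (log2 fold change -8.79 ± 0.56, edgeR adjusted p = 0.0064). Its transcript is 99.5% identical to that of Eno1 over 92.2% of its length, so its level is uncertain, and the sum of Eno1b and its copies was 1228 CPM in WT and 1237 CPM in G643W.

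The other falls were in genes with diverse roles. Zfp990, a zinc finger gene, went from 56.6 to 0.26 CPM, and Arntl2, a circadian transcription factor related to Bmal1, from 26.0 to 1.39 CPM. Camk2b, a calcium-calmodulin dependent kinase subunit, went from 10.8 to 0.16 CPM, Ncmap from 5.95 to 0.11 CPM, Gm20379 from 11.6 to 0.29 CPM and Gm21411 from 1.34 to 0.031 CPM. Their log2 fold changes lay between -7.80 for Zfp990 and -4.22 for Arntl2 (edgeR adjusted p from 0.0257 to 0.0481). For Zfp990 the size depended on the unit, with 12.9 and 1.44 TPM in WT and G643W, and the Zfp990 log2 fold change was -3.28 with length-scaled counts (edgeR adjusted p = 0.399). On the log2(TPM + 1) scale, which shrinks changes of low genes, limma gave -2.53 for Zfp990, -2.52 for Arntl2, -2.54 for Gm20379 and -1.94 for Ncmap. Gm21411 has 9 near-identical copies, so its level is uncertain, and its log2 change summed with them was -1.21. Among the 5 genes with the lowest adjusted p were also the Rpl29-like pseudogene Gm8210, which rose from 1.05 to 127 CPM, the antisense RNA 9330111N05Rik, from 0.19 to 23.8 CPM, and the pseudogene Gm18517, from 3.77 to 50.2 CPM. Gm8210 has 28 near-identical copies and 9330111N05Rik overlaps Gm18517, so these levels are uncertain too. Of protein-coding genes with higher values that did not pass, Hmga1b had 10.5 and 86.7 CPM in WT and G643W, Fhl2 0.022 and 3.19, Fam167a 0.21 and 1.81 and Clic5 0.31 and 5.71, while Gm13290 had no reads in WT and 0.25 CPM in G643W. The span of Fhl2 holds Gm8210, so the rise of Fhl2 may not be separate from that of the pseudogene. For Hmga1b the direction reversed with length-scaled counts (log2 difference -0.23) and with limma on TPM (-0.27).

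All 25 genes kept their direction in every alternative that tested them, but the count did not hold. It was 5, 0 and 15 without WT library 1, 2 or 3 and 16, 6 and 3 without G643W library 1, 2 or 3; without WT library 2, 1277 genes had an unadjusted edgeR p under 0.05, against 1996 with all libraries. DESeq2 called 427 genes (164 higher, 263 lower), the unfiltered edgeR fit 104, length-scaled counts 10, the edgeR fit without a scaling factor 16 and that on protein-coding genes alone 2, Traip and Eno1b.

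**Figure D1:**
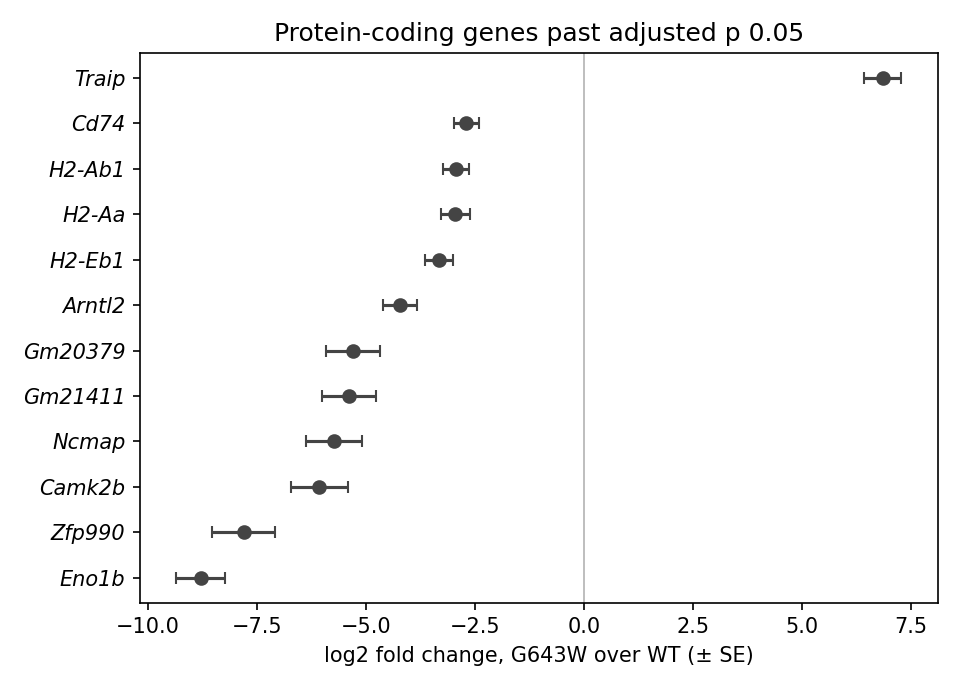
Log2 fold change (G643W over WT, horizontal axis) of the called protein-coding genes named by rule, with bars for the standard error of the edgeR fit. Traip lies at 6.86, while the genes that fell lie between -8.79 for Eno1b and -2.69 for Cd74.

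The antigen presentation genes of MHC class II were lower in G643W blasts. Of the 11 measured members of that list, 4 fell over all genes tested and 7 adjusted over the list alone, none rose, and in 8 every G643W library lay below every WT library, where 15.9% of all tested genes had no overlap in either direction and chance gives 10%. H2-Eb1, a class II beta chain (chromosome 17, 34305867 to 34316674), went from 199 ± 58.1 to 19.97 ± 4.06 CPM (log2 fold change -3.32 ± 0.31, edgeR adjusted p = 0.0257). H2-Ab1 went from 230 ± 69.6 to 30.04 ± 4.33 CPM (-2.93 ± 0.30, edgeR adjusted p = 0.0346), H2-Aa from 271 ± 88.9 to 35.2 ± 6.25 CPM (-2.94 ± 0.32, edgeR adjusted p = 0.0436), and Cd74, the invariant chain (chromosome 18, 60803848 to 60812652), from 790 ± 150 to 122 ± 27.8 CPM (-2.69 ± 0.29, edgeR adjusted p = 0.0428). The list's median log2 change was -1.59 (camera adjusted p = 2.03e-10). With an estimated correlation it was not called (adjusted p = 0.259), and it was the only list past the threshold with fry (adjusted p = 0.0084). All 4 genes missed the threshold without WT library 1, WT library 2 or any G643W library, with the highest adjusted p, from 0.214 for H2-Eb1 to 0.271 for H2-Aa, without G643W library 3. Without WT library 3 only Cd74 missed it (adjusted p = 0.0806). On protein-coding genes alone all 4 missed it (adjusted p from 0.0614 to 0.0771), and all but H2-Eb1 did with length-scaled counts (0.0583 each), without a scaling factor (0.0611 to 0.0638) and with limma on log2 TPM (0.0510 to 0.0608). With the neutrophil mean as a covariate H2-Eb1 (adjusted p = 0.0663) and Cd74 (0.0515) missed it, with log2 fold changes of -3.27 and -2.54. Across these lost calls the log2 fold changes stayed between -3.47 and -2.51.

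**Figure D2:**
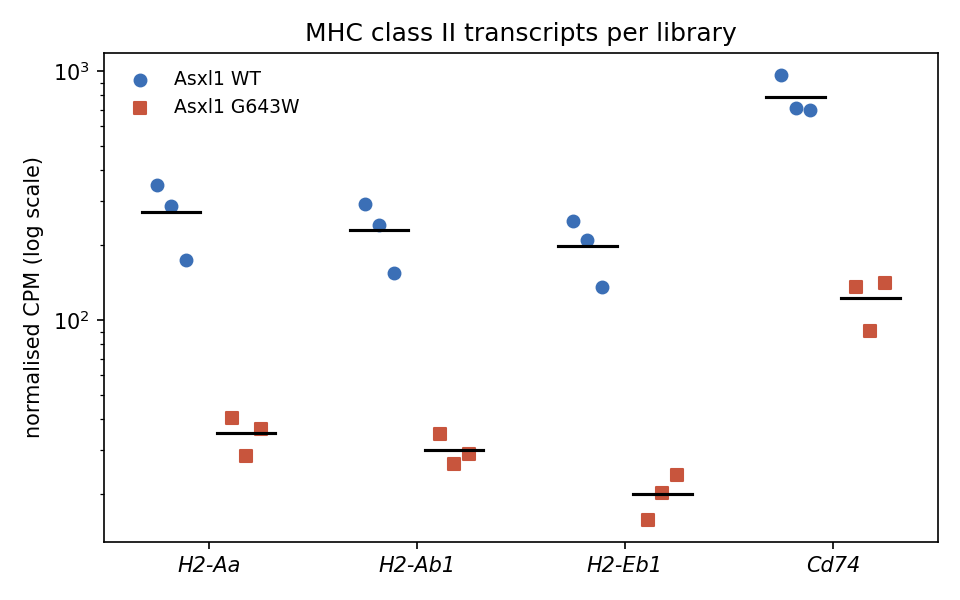
Normalised CPM (log axis) of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 in each of 3 WT (circles) and 3 G643W (squares) libraries, with black lines at the group means. Mean Cd74 was 790 CPM in WT and 122 CPM in G643W, and the groups do not overlap for any of the 4 genes.

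Lists of dendritic cell and monocyte genes also had negative median log2 changes in G643W blasts, with no single member past the threshold over all genes. The 19 dendritic cell genes had a median log2 change of -1.58 (camera adjusted p = 0.0035, and adjusted p = 0.624 with an estimated correlation), and 6 of them fell when adjusted over the list alone. Cd209a, a lectin of monocyte-derived dendritic cells, had 45.0 ± 48.0 and 0.29 ± 0.19 CPM in WT and G643W (edgeR adjusted p = 0.155). The 25 monocyte genes had a median of -1.03 (camera adjusted p = 0.0002, and adjusted p = 0.739 with an estimated correlation), with F13a1 at 894 ± 386 and 213 ± 112 CPM. By the monocyte list's mean log2 CPM relative to all libraries the genotypes overlapped (two-sided exact permutation p = 0.2). G643W library 3 lay at 0.0076, above WT library 3 at -0.12. For the 26 stem and progenitor genes the median was -0.71 (camera adjusted p = 0.0329, and adjusted p = 0.739 with an estimated correlation), with 1 member past the threshold adjusted over the list alone. That member was Flt3, a receptor of early progenitors that is also on the dendritic list, at 29.8 ± 13.8 and 3.63 ± 2.53 CPM. The dendritic list was not called without G643W library 1 (camera adjusted p = 0.161), nor the stem and progenitor list without WT library 1 (0.0811) or G643W library 2 (0.0661). DESeq2 called Cd209a, F13a1 and Flt3 lower (adjusted p = 4.51e-13, 0.0263 and 0.00018).

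Neutrophil genes differed widely between libraries, and the genotypes overlapped. Their mean level relative to all libraries was -2.21, -0.96 and 1.02 log2 units in WT libraries 1 to 3 and -1.80, 2.32 and 1.64 in G643W libraries 1 to 3. The list's median log2 change was 1.45 (camera adjusted p = 0.0027, and adjusted p = 0.784 with an estimated correlation), and none of the 27 members passed; Stfa2l1 had 67.8 ± 61.6 and 1738 ± 1596 CPM. The list was not called without WT library 1 (adjusted p = 0.190) or G643W library 2 (adjusted p = 0.205). Erythroid genes had a median of 1.08 over 15 measured members (camera adjusted p = 0.00085, and adjusted p = 0.739 with an estimated correlation), with 1 member higher adjusted over the list alone, Gata1, at 0.23 ± 0.049 and 1.45 ± 0.68 CPM. Apart from Tfrc, at 89.7 ± 36.1 and 124 ± 66.7 CPM, the measured members had WT means of at most 1.68 CPM. The erythroid call therefore rests mostly on values near the floor. Lists of other cell types did not pass camera: macrophage (median -1.32, adjusted p = 0.086), NK cell (-2.02, 0.187), megakaryocyte (0.63, 0.187), eosinophil (0.46, 0.282), promyelocyte granule (0.39, 0.292), stromal and endothelial (-0.46, 0.508), mast cell and basophil (0.01, 0.522), B cell (-0.24, 0.545) and T cell genes (-0.26, 0.973). The mean log2 change differed in sign from the median for mast cell and basophil (-0.62) and B cell genes (0.07).

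Mitosis genes lay higher and ribosomal protein genes lower in G643W blasts. All 30 genes of the G2 and mitosis list had a positive log2 difference, with a median of 0.96 (camera adjusted p = 7.23e-16, and adjusted p = 0.739 with an estimated correlation). None passed over all genes, 15 rose adjusted over the list alone, and in 24 every G643W library exceeded every WT library, against the same 15.9% of all tested genes. These genes moved together (estimated correlation 0.64), so the 24 are not independent of each other. The list's mean level gave a two-sided exact permutation p = 0.1, the smallest possible. Cenpe, a kinetochore motor, had 50.7 ± 6.85 and 127 ± 24.9 CPM. S phase genes had a median of 0.07 (camera adjusted p = 0.197). All 78 cytosolic ribosomal protein genes had a negative log2 difference, with a median of -0.86 (camera adjusted p = 3.06e-23, and adjusted p = 0.739 with an estimated correlation), and none passed, over all genes or adjusted over the list alone. In 50 of the 78 every G643W library lay below every WT library, but these genes too moved together (estimated correlation 0.89). The mean level of the ribosomal protein list also gave a two-sided exact permutation p = 0.1. Rpl34 had 758 ± 211 and 238 ± 64.9 CPM. Its pseudogene Rpl34-ps1 went the other way, at 26.8, 20.3 and 6.72 CPM in WT and 298, 172 and 179 CPM in G643W libraries. The size of the Rpl34 fall is therefore uncertain. Rpl29 alone had a log2 change of -1.44, while Gm8210 summed with its near-identical copies, Rpl29 among them, had -0.80. Ribosomal protein genes took 7.85, 10.3 and 6.61% of reads in WT libraries 1 to 3 and 7.01, 2.87 and 3.93% in G643W libraries 1 to 3, so by read share G643W library 1 lay within the WT range. By the list's mean log2 CPM relative to all libraries it lay at 0.095, below the lowest WT library at 0.19. Ribosome biogenesis and Myc-driven genes had a median of -0.63 (camera adjusted p = 1.18e-07, and adjusted p = 0.784 with an estimated correlation), but the genotypes overlapped. By mean log2 CPM relative to all libraries this list lay at 0.16, 0.69 and 0.48 in WT libraries 1 to 3 and at 0.50, -1.43 and -0.40 in G643W libraries 1 to 3 (two-sided exact permutation p = 0.3).

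**Figure D3:**
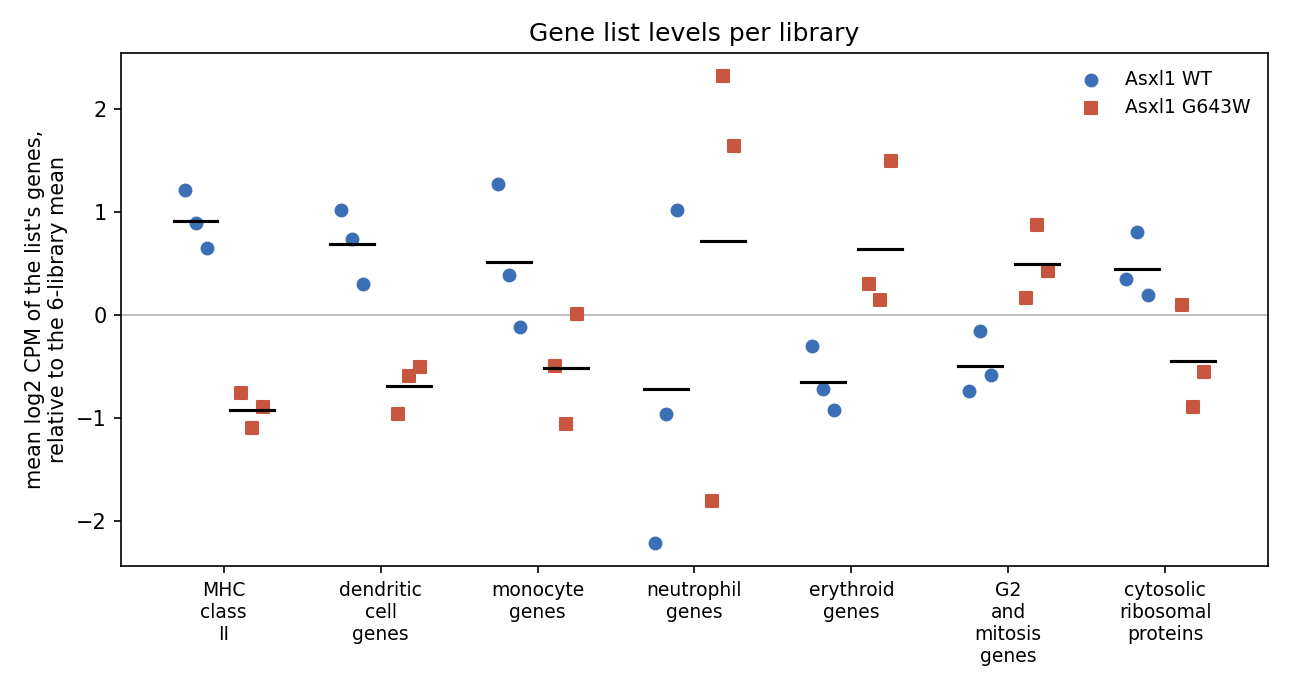
Mean log2 CPM of the genes of 7 lists in each library, relative to the mean of all 6 libraries (vertical axis), for WT (circles) and G643W (squares), with black lines at the group means. Class II means were 0.92 in WT and -0.92 in G643W without overlap, while neutrophil values overlapped, from -2.21 to 1.02 in WT and from -1.80 to 2.32 in G643W.

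Among metabolic and stress genes, 4 further lists passed camera with the preset correlation and none with an estimated correlation. Heat shock genes had a median of -0.67 (adjusted p = 0.0023, and adjusted p = 0.739 with an estimated correlation), with 1 of 12 lower adjusted over the list alone, Hspa1a, at 48.5 ± 36.3 and 0.41 ± 0.47 CPM. Its close relative Hspa1b had 140 ± 137 and 68.0 ± 46.2 CPM, with overlap (log2 difference -1.04). How reads were divided between them was not examined, so the level of Hspa1a is uncertain. Cholesterol synthesis genes had a median of 0.45 (adjusted p = 0.0023, and adjusted p = 0.739 with an estimated correlation). Nuclear-encoded respiratory chain genes had a median of -0.23 (adjusted p = 0.0035) and mitochondrially encoded genes of 0.54 (adjusted p = 0.017), each with an adjusted p = 0.784 with an estimated correlation. Cholesterol genes were not called without WT library 1 (0.0751) or G643W library 1 (0.107), respiratory chain genes without WT library 2 (0.286) or G643W library 3 (0.0736), and mitochondrially encoded genes without WT library 1 (0.187) or G643W library 1 (0.417). Interferon-stimulated genes (median -1.47, adjusted p = 0.064), glycolysis and hypoxia genes (-0.40, 0.082), ATF4 and unfolded protein response genes (-0.32, 0.115), NF-kB and cytokine genes (-0.60, 0.214), p53 targets (-0.19, 0.282), haem and iron genes (-0.16, 0.545), MHC class I (-0.20, 0.562), immediate-early genes (-0.67, 0.737) and adhesion genes (0.30, 0.824) did not pass.

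The chromatin lists tied to Asxl1 did not pass. Genes of the PR-DUB complex, which removes ubiquitin from histone H2A, had a median of 0.08 (camera adjusted p = 0.350), Polycomb PRC1 genes of -0.17 (0.394) and PRC2 genes of 0.01 (0.973), where the mean was -0.16. Developmental regulators held by Polycomb had a median of 0.71 over the 13 of 74 that were measured (0.350), and the Hox and Meis list of -0.15 over 7 of 24 (0.580). C/EBP family and linked myeloid genes had a median of -0.09 (0.973). Within that list 3 rose and 1 fell adjusted over the list alone, and Id1, an inhibitor of helix-loop-helix factors, had 10.4 ± 5.38 and 44.5 ± 5.86 CPM (edgeR adjusted p = 0.230).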

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

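The 25 called genes kept their direction under each alternative that tested them. The neutrophil covariate, the length and GC trend and robust fitting were added after the data had been seen. The count of 25 (11 higher, 14 lower) moved to 16 (8 and 8) without a scaling factor, 104 (37 and 67) without a filter, 10 (8 and 2) with length-scaled counts, 427 (164 and 263) with DESeq2 and 2 (1 and 1) on protein-coding genes alone, where fewer genes were tested. Lower genes numbered 8 with limma on log2(TPM + 0.1) and 8 with the neutrophil covariate. Leaving out a library gave 0 to 16 genes (0 to 13 higher, 0 to 7 lower), where fewer samples entered. With the replicate number as a block there were 0 genes (0 higher, 0 lower), with 1772 at an unadjusted edgeR p under 0.05. The numbers did not pair the libraries, since deviations of same-numbered libraries correlated at 0.11, -0.16 and 0.18, and not every library correlated best with its own number. Other scalings, the stricter filter, limma on log2(TPM + 1), the trend removal and robust fitting gave 23 to 30 genes. Called lists numbered 13, 11 to 17 with a library left out, 0 with an estimated correlation and 1 with fry. Hmga1b log2 fold change reversed to -0.226 with length-scaled counts, -0.2697 with limma on log2(TPM + 1) and -0.2702 on log2(TPM + 0.1); the cause was not tested. The neutrophil list reversed with its own mean as covariate (adjusted p = 0.764), which that covariate's construction brings about. Libraries held 61167075 reads or more, and no lower depth was tried.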

Other observations

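The explanations weighed here were tested after the results they bear on had been seen. The use of the Cebpa transcripts, which was singled out after its values were seen, differed between genotypes. The single-exon Cebpa transcript held 64.0, 55.2 and 64.9% of Salmon's estimated Cebpa reads in WT libraries 1 to 3 and 26.0, 24.6 and 22.98% in G643W libraries 1 to 3. The means were 61.4 ± 5.40% and 24.5 ± 1.5% (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). WT library 1 stood apart in interferon-stimulated genes, at 2.49 log2 units above the mean of all libraries, where the other libraries lay between -1.01 and 0.15, and in immediate-early genes, at 1.86.

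With 3 against 3 there are 10 splits of the libraries, too few for a share under 0.05. The real split called 25 genes and the highest other split 1; it called 13 lists and the highest other split 18, and 6 of the 10 splits, the real one included, called at least 13, while 1 of the 10 called at least 25 genes. At an unadjusted edgeR p under 0.05 the order was different, with 3625 genes for WT libraries 1 and 2 and G643W library 1 against the rest and 1996 for the real split. The first principal component (44.1% of variance) also placed G643W library 1 (-33.0) on the side of WT libraries 1 and 2 (-88.5 and -94.3), and WT library 3 (13.5) on that of G643W libraries 2 and 3 (115.9 and 86.3), which points to a structure of the samples other than genotype. The neutrophil list's mean level divided the libraries in the same way. It was -2.21, -0.96 and -1.80 in WT libraries 1 and 2 and G643W library 1. In WT library 3 and G643W libraries 2 and 3 it was 1.02, 2.32 and 1.64. With fry the real split called 1 list, class II, WT libraries 1 and 2 with G643W library 1 against the rest called 3, and 2 other splits called 1 each. The unadjusted fry p of class II was 0.000222 in the real split and from 0.39 to 0.735 in the others. That contrast adds no support, since class II was picked because the real split called it and every other split mixes the genotypes.

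A first pattern concerns genes separated by a wide margin between the genotypes. With 0.1 CPM added, 71 genes had a lowest library at least 4-fold above the highest of the other group, and 28 of them (39.4%) were pseudogenes, against 9.21% of tested genes (two-sided Fisher's exact p = 7.44e-12). The lower group need not be off, since Cd74, among the 71, had a mean of 122 CPM in G643W. At 8-fold there were 30 with 13 pseudogenes. WT libraries 1 and 2 with G643W library 1 against the rest gave 123 with 7 pseudogenes at 4-fold and 26 with 1 at 8-fold, so at 4-fold the number was not highest for the genotypes. Each remaining split gave at most 7 genes at 4-fold with at most 2 pseudogenes, too few to compare their shares of 0 to 33.3%. Of the 25 called genes, 12 have a near-identical copy, against 13.1% of tested genes, but these hold a median of 8.75% of the CPM summed with their copies. The sums therefore cannot show whether reads moved between copies, which stays open for these genes. The other 13, Traip among them, have no such copy, though the search does not exclude reads shared with less similar genes. DNA sequence differences between the mice of the 2 groups are a candidate explanation that the pseudogene share fits; 22 of the 71 genes lay within 1 Mb of another, against a median of 6 in 10000 random draws, but 41 of 123 did so in the other split, so inherited segments cannot be told apart from local co-expression, and an effect of the Asxl1 genotype stays open and untested.

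A second pattern is the lower class II expression, where a different H2 haplotype in the mutant mice would leave Cd74, on chromosome 18 outside the H2 region, and Ciita, on chromosome 16, at their levels, but the log2 fold change was -2.69 for Cd74, and for Ciita it was -2.39 ± 0.40 SE without overlap (23.5 to 4.49 CPM, adjusted p = 0.176, which did not pass). For the class II genes inside the H2 region a different H2 haplotype cannot be told apart from lower expression. Within 2 Mb of the called H2 genes, 4 other genes, singled out after their values were seen, met the 4-fold rule of the first pattern. Gm7029, Platr17 and Hspa1a were higher in WT and A930015D03Rik in G643W, with at most 2 such genes in another split. Of these, the level of Hspa1a is uncertain, since reads may be divided between it and Hspa1b. The window was also chosen afterwards, but the real split had the most such genes at 0.5, 1, 2 and 5 Mb. At these nested windows the two-sided Fisher's exact p was 0.0165, 0.00748, 0.00417 and 0.0108, which goes with a haplotype. The called H2 genes changed by a mean log2 of -3.07, within 2 standard errors (0.293 each) of Cd74. That bound was set after the values were seen. More mature neutrophils in G643W libraries, whose transcripts were abundant despite the sort for low Mac1 and Gr1 (Ngp at 3307 and 10285 CPM in WT and G643W), would take the difference away once the neutrophil mean is a covariate, but 91.8% of it remained (-1.68 ± 0.12 SE, against -1.83 ± 0.19). Dendritic cells in the WT libraries could account for it, since dendritic cell genes had a median log2 change of -1.58, and 13 of 19 were lower, among them, also singled out, Cd209a (45.0 to 0.289 CPM), Irf4 (13.3 to 0.640), Siglech (3.45 to 0.380), Batf3 (4.01 to 0.213) and Clec10a (26.5 to 8.88), without overlap. The sort was set to exclude B220 and to take low Mac1, but with neutrophil transcripts abundant despite it, it does not exclude dendritic cells, and 6 dendritic genes were higher, Tcf4 (4.24 to 10.7 CPM) among them, with Itgax little changed (22.8 to 19.1), so it cannot be told apart from lower expression in the blasts, where Flt3 and class II genes are not limited to dendritic cells, and the Asxl1 genotype stays open and untested.

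A last pattern is that ribosomal protein genes lay lower while mitosis genes lay higher. With a length and GC trend removed per library, 93.9% of the difference between the lists' mean changes remained (1.77 ± 0.51 SE, against 1.88 ± 0.50), which argues against that trend as the whole cause. With the neutrophil mean as a covariate 79.6% remained (1.496 ± 0.33 SE), which argues against neutrophil maturity as the whole cause, though part of the difference may go with it; the sort took low Mac1 and Gr1, yet the neutrophil gene S100a9 had 7342 and 25245 CPM in WT and G643W, so the sort does not exclude these cells or their RNA. The bound used, that more than 50% of the difference must remain by more than its standard error, was set after related values had been seen. Whether reads moved between ribosomal protein genes and their pseudogenes was not tested for the list, so the size of its fall is uncertain. The Asxl1 genotype stays open and untested, and the list calls were lost with an estimated correlation.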
